A study of Mus musculus with 12 samples.

How the data were processed

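Expression was measured in biopsies of colon tumors of 6 mice with 1 array per biopsy, 12 arrays in all. Per the labels, the mice were F1 hybrids of SWR and C57BL/6 carrying Apc^Min/+, received 2 treatments of 4% dextran sodium sulfate of 4 days each with 17 days of water between, and were left 30 days for tumors to form before colonoscopy every 14 days and biopsy every 28 days. Per the labels, biopsies were put in RLT buffer or in RNALater (which biopsy went into which is not given in the sources used here), and 300 ng of RNA per biopsy was labelled with the Ambion WT Expression kit for Affymetrix arrays. The deposited values of 35557 probe sets were read as log2 intensities, because the labels give no unit and the range and the array medians are those of log2 values. How the authors summarised and normalised the deposited intensities is not given in the sources used here. Values were used as deposited; raw array files were not used here.

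Samples were grouped by time point (early, late) and by final pathology (adenoma or intramucosal carcinoma). The labels give the final pathology for the late biopsies only, and the early biopsy took that of the late biopsy of the same mouse. The pairing of early and late arrays comes from the animal. It was checked on deviations from the mean of the arrays of each time point, so a difference between the pathologies stays in these values. The 2 arrays of a mouse correlated at r = 0.110 to 0.527, in 6 of 6 pairs over 0.1. Of the early arrays, 5 of 6 were best matched by their own late array, that of mouse 2201 being the exception. The recorded sex was checked on Xist, Eif2s3y, Kdm5d and Uty and matched on 12 of 12 arrays. The correlation of an array with the others had a median between 0.973 (late biopsy of mouse 1805) and 0.988.

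Of the probe sets, 21789 carry 1 gene symbol, 1621 several and 12147 none. Symbols were matched by gene identifier to a RefSeq gene table for the mouse for 21698 probe sets, which changed 0 symbols. Probe sets with 1 symbol were used, and the probe set with the highest mean over all arrays was kept for the 999 genes with more than 1, which left 19938 genes. No filter on dim genes was applied.

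Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a common prior, 2-sided moderated t, Benjamini-Hochberg adjustment over the genes of a comparison, threshold 0.05). Late was compared with early over all 6 mice with mouse as a fixed block. The change in adenoma tumors, the change in carcinoma tumors and the difference of these changes came from 1 fit with the same block. Carcinoma was compared with adenoma at each time point in a fit of 4 groups over all 12 arrays with mouse as a random block (duplicateCorrelation, consensus correlation 0.286). Residual degrees of freedom were 5 for late against early, 4 for the changes by pathology and 8 for the comparisons between pathologies. Errors given as SE are those of the moderated t, and ± is the SD over mice. Adjusted p values in the report are those of limma for genes and those of cameraPR, also from limma, for lists.

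The 33 gene lists of cell types and pathways, together 397 genes of which 359 were measured, and 9 fixed genes (Apc, Ctnnb1, Myc, Lgr5, Axin2, Mki67, Muc2, Krt20, Pla2g2a) were written down before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. Lists were tested with cameraPR on the moderated t at a preset correlation of 0.01, 2-sided, with adjustment over the lists of a comparison, and again with the correlation between genes estimated from the residuals. A list needed 5 measured genes; the erythroid list, with 2 measured, and the sex and reference genes were not tested, which left 30. Where members of a list are called adjusted over the list alone, the Benjamini-Hochberg adjustment was made over the members of that list. For late against early the mean change of a list per mouse was also put to an exact sign-flip test over 64 arrangements, whose smallest possible p is 0.03125. The other genes on these lists are not analysed here.

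The naming rule took, for late against early over all tumors, up to 12 genes per direction with the largest difference among those past the threshold with the same direction in 6 of 6 mice, and otherwise the smallest unadjusted p until 6 per direction were named. For each comparison by pathology it took up to 8 per direction past the threshold, filled up to 4 by the smallest unadjusted p. Predicted genes, microRNAs, small nucleolar RNAs, olfactory and vomeronasal receptors and receptor segments were counted but not named, and the mean had to lie above the 25th percentile. Of each list up to 4 members with the smallest unadjusted p could be named, and the fixed genes are given in every comparison. Outside this rule, Fzd10 in adenoma tumors and the genes of sets of up to 3 called under an alternative were named after their values were seen, except for small nucleolar RNAs.

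An array group was found after the data had been seen, from the mean of the 50 lowest-numbered probe sets, of which 0 carry a gene name. That they are array controls is background knowledge and not stated in the table. The number 50 was settled on after other numbers had been looked at. Of these 50 probe sets, 48 were higher on the 4 early arrays of mice 1755, 1803, 1805 and 2201 than on the other 8 arrays (means over the group), the gap between the array groups was 0.140, and the next widest gap was 0.0577. The array group as a term was therefore added as an alternative chosen after seeing the data.

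The other alternatives were no mouse block, only the arrays of the time point in place of the random block, sex or age as a covariate, age in days in place of the time point, leaving out the dimmest 25% or 50% of genes, all probe sets, the mean of the probe sets of a gene, quantile normalization, centring each array on its median, eBayes with trend and robust settings, array weights, and leaving out each mouse in turn. Other splits of the samples were run for each count. The scripts were tested on simulated data: of 74 genes changed by 1 log2 among 19938, 93.2% were recovered for late against early, 79.7% for the adenoma tumors and 82.4% for late carcinoma against adenoma, with 10, 8 and 7 false calls over all changed sizes. For changes of 0.5 log2 these shares were 69.2%, 27.7% and 35.4%. The changed genes were drawn at random, with independent noise of each gene's own spread and no array group. The shares do not hold for noisier genes: the median SE for late against early was 0.0738, and genes named below such as Eng and Mcpt1 had larger ones. Of 600 unchanged simulated lists, 7.83% had an unadjusted cameraPR p under 0.05 at the preset correlation when genes were independent. This share was 42.2% when they were correlated at 0.5. With the estimated correlation these shares were 9% and 4.83%. In the real data the lists called for late against early had estimated correlations from 0.31 (matrix proteases) to 0.78 (mast cells). A call at the preset correlation alone is therefore no evidence of a change.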

Results

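Expression was measured in biopsies of colon tumors taken by colonoscopy from living mice, at the first and at the last look at each tumor. The animals were F1 hybrids of the SWR and C57BL/6 strains that carried the Min mutation in one copy of Apc, a suppressor of the Wnt pathway, and had received dextran sodium sulfate, a polymer that injures the colon lining, after weaning. One early and one late biopsy of 1 tumor in each of 6 mice were hybridised to Affymetrix mouse gene arrays, 12 arrays in all, so that each late array has an early partner from the same animal. Mice were 94.3 ± 11.8 days old at the early biopsy (SD, n = 6) and 280.0 ± 82.5 days old at the late one (SD, n = 6). The late biopsy was read as adenoma, a benign tumor, in mice 1755, 1803 and 1805, and as intramucosal carcinoma, a cancer that has not left the mucosa, in mice 2201, 3407 and 3413. Early biopsies carry no reading of their own and were grouped by the final pathology of the tumor. Late adenoma biopsies came from mice of 333 ± 86.4 days (SD, n = 3) and late carcinoma biopsies from mice of 227 ± 35.2 days (SD, n = 3), so pathology and age at the late biopsy go together in part. The median of an array lay between 7.62 log2 (early biopsy of mouse 1755) and 7.80 log2 (late biopsy of mouse 3413). The number of arrays, 3 mice per pathology, limits the precision of every comparison. Xist, the transcript that silences an X chromosome in females, was at 13.15 ± 0.11 log2 in the 4 arrays from females and at 5.92 ± 0.22 in the 8 from males (SD), and it and the Y-linked genes Eif2s3y, Kdm5d and Uty matched the recorded sex on 12 of 12 arrays.

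The arrays also fell into 2 groups on probe sets that name no gene. The mean of the 50 lowest-numbered probe sets was 7.08 to 7.19 log2 on the early arrays of mice 1755, 1803, 1805 and 2201, and 6.80 to 6.94 on the other 8 arrays. The gap between these array groups was 0.140, and the next widest gap between arrays was 0.0577. The submitters' own sample numbers run from 155 to 255 in the first array group and from 319 to 379 in the second. All 6 late arrays lie in the second array group. The pairs of all 3 adenoma mice and of mouse 2201 cross the array groups, and the pairs of mice 3407 and 3413 lie within the second.

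The first comparison asked how the late biopsy of a tumor differed from the early biopsy of the same tumor, over all 6 tumors. Transcripts of blood vessels, stroma and neutrophils were higher in the late biopsies, and those of mast cells were lower, at the preset correlation. These calls were lost, at adjusted p = 0.823 with an estimated correlation. The 10 measured endothelial genes rose as a list by a median of 0.89 log2 (list level 9.02 ± 0.58 early and 9.80 ± 0.13 late, SD, n = 6 each). All 10 were higher, 7 of them past the threshold adjusted over the list alone and 0 over all genes. Eng, a co-receptor for TGF-beta family ligands, was 1.26 higher (SE 0.345) and Vwf, the adhesive glycoprotein that endothelial cells store, 0.90 higher (SE 0.226), each in 5 of 6 mice. The 17 genes of fibroblasts and matrix rose by a median of 0.68, all 17 in the same direction but 0 of them past the threshold adjusted over the list alone. The gelatinase Mmp2 was 1.01 higher (SE 0.30) and the small proteoglycan Bgn 0.95 higher (SE 0.291). Neutrophil genes rose by a median of 0.90, with 11 of 12 higher and 3 past the threshold adjusted over the list alone. Among these were the granule protein Ngp at 0.91 (SE 0.220) and the collagenase Mmp8 at 1.54 (SE 0.435). Mast cell genes fell by a median of 1.01, with 8 of 9 lower. The mast cell proteases Mcpt1, at -2.60 (SE 0.651), and Mcpt2, at -1.91 (SE 0.505), were lower in 6 of 6 mice and passed adjusted over the list alone. The mean of the matrix list was 0.44 without mouse 1803, in place of 0.68, and that of the neutrophil list 0.54 without mouse 1805, in place of 0.82. The mast cell mean was -0.65 without mouse 1755, and its call ended without mouse 1805 (-0.94), 3407 (-0.92) or 3413 (-1.02). The 2 measured erythroid genes, too few for a test, had a mean change of 1.29, with 5 of 6 mice above 0. Mouse 1805 had the highest value of both the erythroid (4.03) and the neutrophil list (2.26), and mouse 2201 the only negative one of both (-0.52 and -0.60).

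A further 6 lists passed with smaller shifts. The inflammatory and mucosal defence list rose by a median of 0.27 with 12 of 17 genes higher and 0 past the threshold adjusted over the list alone. The antimicrobial lectins Reg3g and Reg3b were at 1.90 (SE 0.441) and 2.07 (SE 0.617). Mesenchymal transition genes rose by 0.27, with 9 of 9 higher and 1 past the threshold adjusted over the list alone. This was Snai1, a repressor of epithelial adhesion genes, at 0.75 (SE 0.195). Matrix proteases rose by 0.29 (10 of 11 higher) and macrophage genes by 0.20 (9 of 13 higher), with 0 of either past the threshold adjusted over the list alone. Cell cycle genes fell by 0.10, with 25 of 29 lower and 0 past the threshold adjusted over the list alone. Oxidative phosphorylation genes also fell by 0.10, with 10 of 13 lower and 1 past it, Ndufs1, a subunit of respiratory complex I, at -0.31 (SE 0.0708). Adjusted p for the 10 lists ran from 4.39e-09 to 0.034 at the preset correlation. Their estimated correlations were 0.31 to 0.78, far above the preset 0.01. Of unchanged simulated lists correlated at 0.5, 42.2% had an unadjusted cameraPR p under 0.05 at the preset setting, so these p values are too small. Every one of these calls was lost, at adjusted p = 0.823 with an estimated correlation. With one mouse left out, the call ended for mucosal defence without mouse 1805 (mean 0.21) or 3407 (0.27), in place of 0.44. It ended for matrix proteases without mouse 1803 (0.22), 1805 (0.13) or 3407 (0.27), in place of 0.33, and for macrophages without mouse 2201 (0.060), in place of 0.22. Cell cycle genes did not pass without mouse 1805 (-0.049), 2201 (-0.073) or 3407 (-0.11), nor oxidative phosphorylation genes without mouse 1803 (-0.076) or 1805 (-0.066). An exact sign-flip test of the mean change per mouse, two-sided over 64 arrangements, cannot go below p = 0.03125. It gave no list a p under 0.05, the smallest being 0.0938. The median, the mean and the test had the same sign in all 10 called lists and differed in sign in 5 of the 20 others, such as the goblet cell list with a median of 0.09 and a mean of -0.30.

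The endothelial change was 1.20 ± 0.157 log2 (SD) in the 4 pairs that cross the array groups and -0.05 ± 0.0937 in the 2 pairs within one. The fibroblast and matrix change was 1.05 ± 0.561 in the first and -0.08 ± 0.567 in the second. With the array group as a term the estimate is the mean of those 2 pairs, of mice 3407 and 3413, both with carcinoma, and 3 lists passed in place of 10. Besides the 2 lists above, the mean turned to -0.07 for mesenchymal transition, -0.04 for macrophages and 0.01 for oxidative phosphorylation. Mast cell genes, at -1.14, and mucosal defence genes, at 0.65, passed, and neutrophil (0.54), matrix protease (0.073) and cell cycle genes (-0.0093) did not. Without mouse 3407, 6 lists passed.

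**Figure D1:**
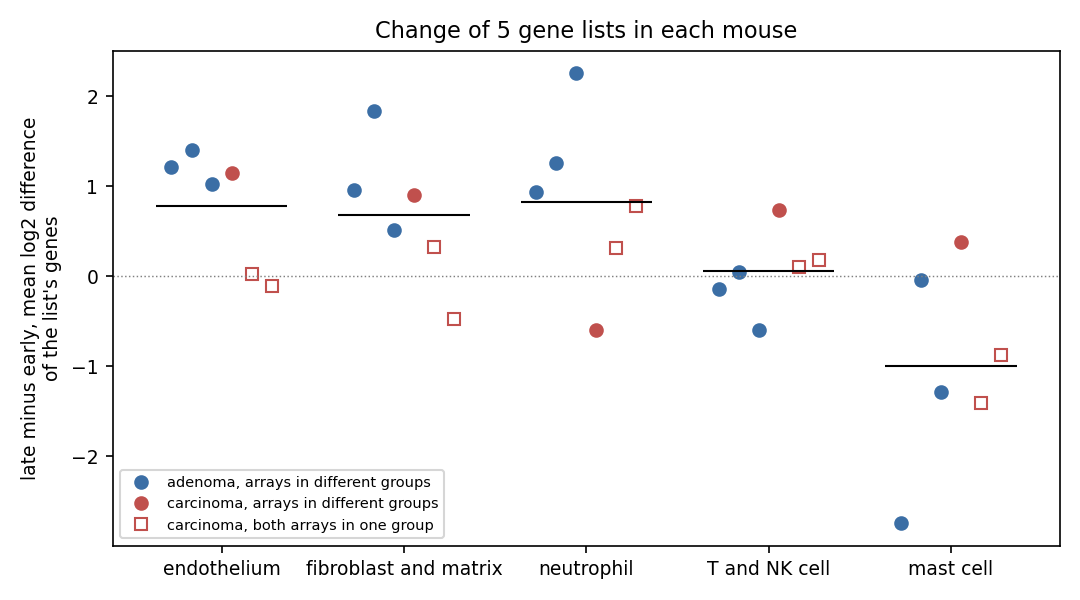
Mean late minus early change (log2, vertical axis) of 5 gene lists in each of 6 mice, with filled circles for pairs whose arrays lie in different array groups, open squares for pairs within one, and a black line at the mean of the 6. The endothelial change lies between 1.02 and 1.40 in the 4 pairs that cross the array groups and between -0.11 and 0.02 in the other 2.

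Single genes did not reach the threshold over all tumors. limma called 0 of 19938 genes, with the smallest adjusted p at 0.168. An unadjusted p under 0.05 was reached by 2940 genes (1133 higher late, 1807 lower), where 996.9 would by chance. Ranked by p, the leading genes were higher or lower in 6 of 6 mice. Lypd6, a membrane-anchored protein that enhances Wnt signalling, was at 7.67 ± 0.37 early and 6.61 ± 0.27 late (difference -1.06, SE 0.101, adjusted p = 0.168), and its paralog Lypd6b at -1.01 (SE 0.119). The organic anion exporter Abcc2 was at -1.57 (SE 0.193), the neuronal pentraxin Nptx1 at -0.84, the neuropeptide Npy at -0.51 and Idi1, an enzyme of isoprenoid synthesis, at -0.43. Among higher genes, Hmcn1, an extracellular matrix protein, was at 8.36 ± 1.09 early and 10.01 ± 0.43 late (difference 1.65, SE 0.232). Brinp1 was at 0.79, the water channel Aqp5 at 0.60, the pseudogene Rdh18-ps at 0.56, and the kinase Dapk1 and the protocadherin Pcdhb7 each at 0.36. The tumor's initiating gene Apc differed by 0.00 (SE 0.0493), and in its pathway Ctnnb1 differed by -0.13 and Myc by -0.13. Axin2 differed by -0.26, with -1.13 in mouse 1805 and -0.28 to 0.08 in the other mice. The stem cell receptor Lgr5 was 0.67 higher (SE 0.233, adjusted p = 0.279), in 5 of 6 mice. The proliferation marker Mki67 differed by 0.03, the mucin Muc2 by -0.16, the keratin Krt20 by -0.40 and the phospholipase Pla2g2a by -0.16. Taking age in days as a continuous term called 33 genes, 12 higher and 21 lower with age, in place of 0. Without mouse 3407 limma called 2 genes, Tbx1 (-1.21) and Lypd6b (-1.13), named after their values were seen.

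The next comparison took the 3 tumors read as adenoma at the late biopsy, and asked which genes differed between the early and late biopsy of the same tumor. Here 25 genes passed, 7 higher and 18 lower in the late biopsies, and the named ones moved the same way in 3 of 3 mice. Hp (probe set 10581605), haptoglobin, an acute-phase protein that binds free hemoglobin, rose 7.07-fold, from 7.06 ± 0.35 log2 to 9.88 ± 0.24 (difference 2.82, SE 0.266, adjusted p = 0.0378). C5ar1 (10560242), the receptor for the complement fragment C5a on myeloid cells, rose by 1.27 (SE 0.134, adjusted p = 0.0462), and Egfl7 (10470283), a protein secreted by endothelial cells, by 0.98 (SE 0.0927, adjusted p = 0.0378). Gulo (10420899), the enzyme of the last step of vitamin C synthesis, fell by 2.38, from 9.88 ± 1.20 to 7.50 ± 1.17 (SE 0.208, adjusted p = 0.0355). The Wnt ligands Wnt10a (10347497) and Wnt6 (10347491) each fell by 1.26 (SE 0.0984 and 0.122, adjusted p = 0.0292 and 0.0401). Lypd6 (10472034) fell by 1.29 (SE 0.0846, adjusted p = 0.0292). The Wnt receptor Fzd10, chosen after its value was seen, fell by 0.84 (SE 0.0923, adjusted p = 0.0491).

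The other named genes that rose were Ddah1, which degrades the nitric oxide synthase inhibitor dimethylarginine (1.34), the semaphorin Sema6d (1.29), the transcription factor Glis3 (1.25) and the ectoenzyme Bst1 (1.12). Those that fell were the trypsin inhibitor Spink1 (-1.46), Fer1l6 (-1.33), the vault RNA gene Vaultrc5 (-1.23) and the aromatic amino acid transporter Slc16a10 (-1.17). Small nucleolar RNAs, counted but not named, were also among the genes that fell (-1.43 and -1.46). Of the fixed genes none passed: Axin2 was at -0.49 (SE 0.190), Pla2g2a at -0.36, Lgr5 at 0.38, Myc at -0.23, Ctnnb1 at -0.17, Krt20 at 0.13, Mki67 at 0.09, Apc at 0.04 and Muc2 at -0.01. At an unadjusted p under 0.05 there were 3597 genes, 1472 higher and 2125 lower.

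**Figure D2:**
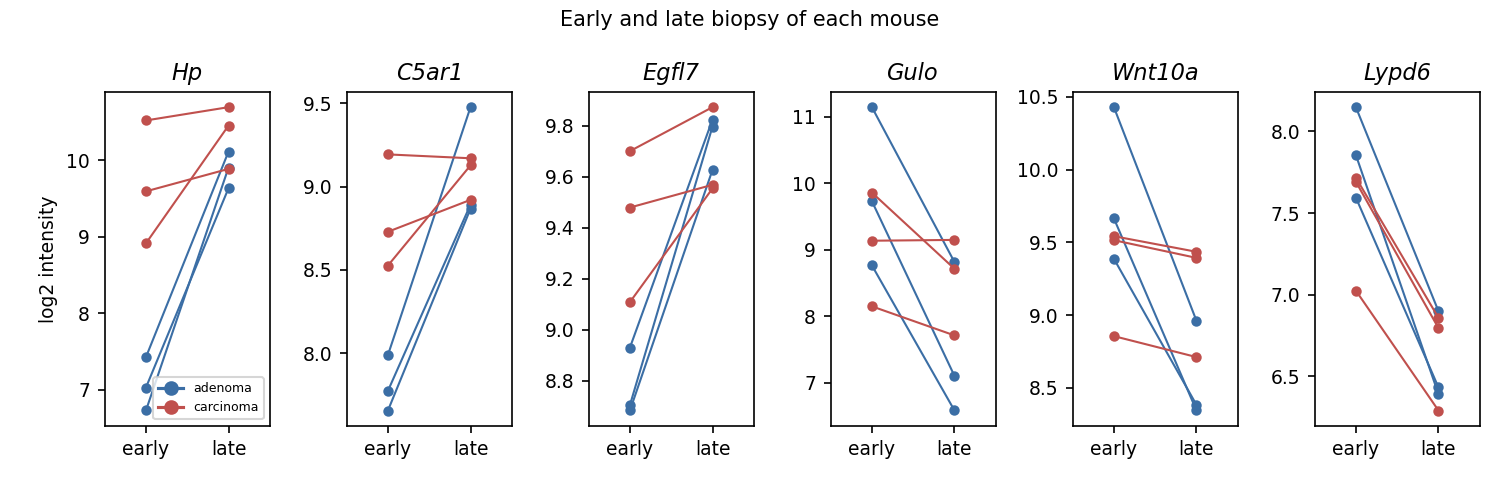
Log2 intensity (vertical axis) of Hp, C5ar1, Egfl7, Gulo, Wnt10a and Lypd6 in the early and the late biopsy of each mouse, joined by a line, in blue for tumors with final pathology adenoma and in red for intramucosal carcinoma. Hp goes from a mean of 7.06 to 9.88 and Gulo from 9.88 to 7.50 in the 3 adenoma tumors.

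In all, 10 lists passed in the adenoma tumors, and the stromal, vascular and neutrophil lists shifted by more than over all tumors. All 10 calls were lost, at adjusted p = 0.669 with an estimated correlation for the matrix, neutrophil, endothelial and mesenchymal lists and 0.794 for the other 6. Matrix genes rose by a median of 1.03, with 17 of 17 higher and 13 past the threshold adjusted over the list alone. Among them were the collagen chains Col1a1 (1.67, SE 0.324) and Col6a3 (1.69, SE 0.343) and the pericyte receptor Pdgfrb (1.59, SE 0.348). Neutrophil genes rose by a median of 1.66, with 11 of 12 higher and 9 past it, including the chemokine receptor Cxcr2 (2.19, SE 0.428) and Csf3r, the receptor for granulocyte colony-stimulating factor (1.52, SE 0.281). In mice 1755, 1803 and 1805 the mean change was 0.93, 1.26 and 2.26 for neutrophil genes, and 1.04, 1.88 and 4.03 for the 2 erythroid genes, which were not tested. Endothelial genes rose by a median of 1.34, with 10 of 10 higher and 7 past the threshold adjusted over the list alone, such as Emcn (1.98, SE 0.372) and Tie1 (1.29, SE 0.222). Wnt targets fell by a median of 0.49, with 15 of 19 lower. The mean per mouse was -0.29, -0.10 and -1.10 in mice 1755, 1803 and 1805, and the mean was -0.20 without mouse 1805, in place of -0.50. Of these, 2 passed adjusted over the list alone, the Wnt inhibitor Apcdd1 (-1.80, SE 0.343) and Bambi (-0.80, SE 0.140). The Wnt-deactivating esterase Notum was at -1.06 (SE 0.302). Mast cell genes fell by 1.44, with 9 of 9 lower and 0 past the threshold adjusted over the list alone. Mcpt1 was at -3.29 (SE 0.907). The mast cell mean per mouse was -2.75, -0.04 and -1.29, and without mouse 1755 the call ended, with a mean of -0.67 in place of -1.36. The mesenchymal transition list rose by 0.49 (9 of 9) and mucosal defence by 0.57 (13 of 17), each with 1 gene past the threshold adjusted over the list alone, Snai1 (1.14) and the serum amyloid Saa3 (1.38). Matrix proteases rose by 0.64 (11 of 11) and hypoxia and glycolysis by 0.27 (12 of 13, with Car9, a hypoxia-induced carbonic anhydrase, at 0.93), with 0 genes past it. Oxidative phosphorylation fell by 0.17 (12 of 13), with 1 gene past it, Ndufs1 (-0.42). Mucosal defence did not pass without mouse 1805 (mean 0.16) or 3413 (0.64), and had a mean of 1.03 without mouse 1803, in place of 0.64. Matrix proteases did not pass without mouse 1803 (0.58) or 1805 (0.36), and were at 1.12 without mouse 1755, in place of 0.69. The hypoxia list was at 0.64 without mouse 1755 and lost its call without mouse 1805 (-0.060), in place of 0.32. Oxidative phosphorylation lost its call without mouse 1805 (-0.12), in place of -0.15. Adjusted p ran from 5.9e-12 to 0.0369 at the preset correlation. Among lists that did not pass, 4 of 20 had a median, mean and test of differing sign.

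All 3 adenoma pairs cross the array groups, so no pair within one array group gives a value, and a term for the array group rests on the carcinoma pairs alone. With that term limma called 0 genes (1142 at an unadjusted p under 0.05), and the calls ended for the matrix (mean 0.12), endothelial (0.02), mesenchymal (-0.08), matrix protease (0.99) and oxidative phosphorylation (-0.05) lists. Neutrophil genes had a mean of 2.62 (in place of 1.48), mast cell genes -2.87 (-1.36) and Wnt target genes -0.45. Mucosal defence was at 1.89 (0.64) and hypoxia at 0.70 (0.32). These are no corrected values, since the term takes off the change of mouse 2201 less that of mice 3407 and 3413. In these mice Hp changed by 0.29, 1.54 and 0.17 and Gulo by 0.01, -0.44 and -1.15, so their adenoma changes grew. Egfl7 changed by 0.45, 0.09 and 0.17 and C5ar1 by 0.60, 0.19 and -0.02, so theirs shrank. The lost gene calls do not show that the array group accounts for these genes. The count of 25 became 0 without mouse 1755 (2391 at an unadjusted p under 0.05), 1803 (3328) or 1805 (2979), 78 without 2201, 2 without 3407 (Tbx1, Hp) and 3 without 3413 (Boc, Gulo and a small nucleolar RNA). It was 2 (Fzd10, Zfp758; these small sets were named after their values were seen) without the mouse block, 13 and 9 without the dimmest 25% and 50% of genes, 7 over all probe sets, and 42 (6 higher, 36 lower) with each array centred on its median.

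The same question was asked of the 3 tumors read as intramucosal carcinoma at the late biopsy. T cell, stem cell and Paneth cell genes were higher in the late biopsies and squamous genes lower, by small amounts and at the preset correlation. These calls, and all 8 in this comparison, were lost, at adjusted p = 0.961 with an estimated correlation. The macrophage and monocyte list rose by a median of 0.32, with 13 of 13 higher, but its mean per mouse was 1.00, -0.05 and -0.04 in mice 2201, 3407 and 3413. The T and NK cell list rose by 0.29, with 11 of 14 higher. Among the latter were Cd3g, a chain of the T cell receptor complex, at 1.20 (SE 0.480), and Foxp3, the regulatory T cell factor, at 0.54 (SE 0.236). The stem cell list rose by 0.22, with 12 of 14 higher. Lgr5 was at 11.69 ± 0.83 early and 12.65 ± 0.20 late (difference 0.96, SE 0.313, adjusted p = 0.952) in 3 of 3 mice. Paneth cell genes rose by 0.55 (6 of 7 higher), with the antimicrobial proteins Ang4 at 0.97 (SE 0.445) and Lyz1 at 1.02 (SE 0.588). Endothelial genes rose by 0.40 (10 of 10), matrix genes by 0.24 (15 of 17) and MHC class II genes by 0.73 (6 of 6). Squamous genes fell by 0.22 (10 of 12), led by the desmosomal cadherin Dsg3 at -1.01 (SE 0.257). Without mouse 2201, 6 lists passed, and only 1 of these 8, the stem cell list. Its removal ended the calls for endothelium (mean -0.046, in place of 0.35), matrix (-0.079, 0.25), macrophages (-0.041, 0.31), MHC class II (-0.24, 0.70), T and NK cells (0.14, 0.34), Paneth cells (0.57, 0.53) and squamous genes (-0.21, -0.38). Without mouse 3413 the means were 0.59 for endothelium, 0.61 for matrix and 0.48 for macrophages, and the calls ended for Paneth cells (0.56) and MHC class II (0.95). Without mouse 3407 they were 0.48 for macrophages and 1.39 for MHC class II, and the calls ended for Paneth (0.47) and stem cells (0.042, in place of 0.16). The MHC class II call also ended without mouse 1803 (0.70).

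None of these 8 lists had a member past the threshold adjusted over the list alone. Their adjusted p ran from 0.00457 to 0.0477 at the preset correlation, and was 0.961 for all 8 with an estimated correlation. In 8 of the 22 lists that did not pass, median, mean and test differed in sign. limma called 0 genes, with 858 at an unadjusted p under 0.05 (338 higher, 520 lower), fewer than the 996.9 that chance would give. The genes with the smallest p, each in the same direction in 3 of 3 mice, were Pld5, of the phospholipase D family, at 6.46 ± 0.02 early and 7.67 ± 0.15 late (difference 1.21, SE 0.114, adjusted p = 0.330), Hmcn1 at 1.97 (SE 0.304, adjusted p = 0.952), the tubulin polyglutamylase Ttll7 at 0.46 and Rdh18-ps at 0.62. Lower were Lypd6 at -0.83 (SE 0.0846, adjusted p = 0.330), Nhs at -0.64, the annexin Anxa10 at -0.97 and the ephrin Efna2 at -0.44. Krt20 was at -0.93 (SE 0.630), Muc2 at -0.30, Ctnnb1 at -0.08, Pla2g2a at 0.05, and Apc, Axin2, Myc and Mki67 each at -0.03.

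The pair of mouse 2201 is the only one of the 3 that crosses the array groups. A term for the array group therefore gives the same list values as leaving out that mouse, and is not a second test. Stem cell genes, at 0.22, were the one list of the 8 that still passed. Without mouse 1805 limma called 1 gene in place of 0, Ibsp, named after its value was seen (-1.65, SE 0.0873). The 8 lists became 4 without the dimmest 50% of genes, 5 over all probe sets and 5 with array weights, 3 of these among the 8.

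Whether the late-early change itself differed between the pathologies was tested as an interaction. The changes compared span unequal times. The 2 biopsies lay 140, 282 and 309 days apart in adenoma mice 1755, 1803 and 1805. In carcinoma mice 2201, 3407 and 3413 they lay 172, 128 and 83 days apart. This interval was not a term in the fit, so a difference between pathologies may also be one of interval. At the preset correlation neutrophil, stromal and vascular genes gained less in carcinoma than in adenoma tumors. Wnt target, Paneth and T cell genes differed the other way. All 12 calls were lost, at adjusted p = 0.739 with an estimated correlation for 10 lists, 0.828 for MHC class II and 0.831 for hypoxia. The neutrophil list changed by 1.48 ± 0.69 in adenoma and 0.16 ± 0.70 in carcinoma tumors (SD, n = 3 each), a median difference of -1.53 with all 12 genes lower. The 2 erythroid genes, not tested, had a mean change of 1.04, 1.88 and 4.03 in the adenoma mice and -0.52, 1.02 and 0.27 in the carcinoma mice. Csf3r (-1.49, SE 0.397) and Ngp (-1.0, SE 0.267) passed adjusted over the list alone. The matrix list differed by a median of -0.79 (0 of 17 genes higher) and the endothelial list by -0.90 (0 of 10 higher). Col6a3 was at -1.90 (SE 0.485) and Emcn at -1.55 (SE 0.527). In late biopsies neither list was called. Matrix was at 11.02 ± 0.20 in adenomas and 10.94 ± 0.05 in carcinomas, and endothelium at 9.84 ± 0.11 and 9.77 ± 0.16 (SD, n = 3 each). These 2 differences, the rise in adenoma tumors and the difference in early biopsies share the same 3 early adenoma arrays and are not separate results. Wnt targets had a mean change of -0.50 ± 0.53 in adenoma and 0.02 ± 0.09 in carcinoma tumors, a median difference of 0.56, with 16 of 19 higher and Apcdd1 at 1.49 (SE 0.486), and Paneth cell genes by 1.29, with 7 of 7 higher and Mptx1, a mucosal pentraxin, at 3.80 (SE 1.30). Without mouse 1805 the mean differences were 0.21 for Wnt targets, in place of 0.51, and 1.00 for Paneth cells, in place of 1.69. T and NK cell genes differed by 0.41 (11 of 14 higher, the cytotoxic granule protease Gzmb at 2.06), MHC class II by 1.28 (6 of 6), stem cell genes by 0.33 (12 of 14) and oxidative phosphorylation by 0.13 (12 of 13). Mesenchymal transition differed by -0.47 (7 of 9 lower), hypoxia and glycolysis by -0.29 (13 of 13 lower) and matrix proteases by -0.83 (9 of 11 lower). MHC class II changed by -2.19 in mouse 1805 and 2.58 in mouse 2201. Its mean difference of 1.26 became 0.44 without the first and 0.32 without the second, and 1.55 without mouse 1803, all 3 ending the call, and 1.95 without mouse 3407. The T and NK cell call ended without mouse 1805 (0.39) or 2201 (0.37), in place of 0.57. The stem cell call ended without mouse 1805 (0.041) or 3407 (0.076), and the mean was 0.32 without mouse 1755, in place of 0.19. The oxidative phosphorylation call ended without mouse 1803 (0.12) or 1805 (0.097), in place of 0.13. The matrix mean was -0.49 without mouse 1803 or 3413, in place of -0.85. The mesenchymal transition call ended without mouse 1803 (-0.27) or 3413 (-0.21), and the mean was -0.64 without mouse 2201, in place of -0.43. The hypoxia call ended without mouse 1805 (0.0082), 2201 (-0.25) or 3407 (-0.40), and the mean was -0.69 without mouse 1755, in place of -0.38. The matrix protease call ended without mouse 1803 (-0.61), 1805 (-0.38), 2201 (-0.61) or 3413 (-0.50), and the mean was -1.15 without mouse 1755, in place of -0.71.

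Apart from the 2 neutrophil genes, no member of these 12 lists passed adjusted over the list alone. Adjusted p ran from 1.33e-07 to 0.0462 at the preset correlation, and none of these calls was kept with an estimated correlation. limma called 0 genes, with 1404 at an unadjusted p under 0.05 (733 higher, 671 lower). Spink1 changed by -1.46 ± 0.26 in adenoma and 0.41 ± 0.41 in carcinoma tumors (difference 1.87, SE 0.233, adjusted p = 0.456). Pld5 changed by -0.22 ± 0.26 and 1.21 ± 0.16 (difference 1.43, SE 0.161), Wnt10a by -1.26 ± 0.24 and -0.12 ± 0.02 (difference 1.14, SE 0.139), and the clock repressor Nr1d2 by -0.46 and 0.45 (difference 0.91). In the other direction were Ddah1 (-1.47), Sema6d (-1.17), Bst1 (-1.11) and Cdr2l (-0.65). Krt20 lay at -1.05 (SE 0.891), with 0.58 for Lgr5, 0.47 for Axin2, 0.42 for Pla2g2a and -0.29 for Muc2. The others were at 0.20 for Myc, -0.12 for Mki67, 0.09 for Ctnnb1 and -0.07 for Apc. Of the carcinoma pairs only that of mouse 2201 crosses the array groups, so a term for the array group leaves the difference between that mouse and the 3 adenoma mice. With the array group as a term the calls ended for endothelium (mean -0.06), matrix (-0.20), mesenchymal transition (0.01), stem cells (0.08), oxidative phosphorylation (0.05) and matrix proteases (-0.91). Neutrophil genes were at -2.08 (in place of -1.32), MHC class II at 3.14 (in place of 1.26) and hypoxia at -0.62 (in place of -0.38). T and NK cell genes were at 0.97 (in place of 0.57), Wnt targets at 0.48 and Paneth cell genes at 1.62. With mouse 2201 as the only carcinoma mouse left, these are sizes only and no test of a pathology difference.

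The late biopsies carry the pathology reading themselves, and all 6 lie in one array group. Carcinomas had on average lower transcripts of differentiated colon epithelium and higher transcripts of cell division and Wnt signalling than adenomas, at the preset correlation. These 4 calls were lost, at adjusted p = 0.577 with an estimated correlation. The pathologies overlapped in all 4 lists. The late adenoma of mouse 1803 was at 9.62 for absorptive genes (carcinomas 9.02 to 9.76) and at 10.88 for goblet genes (10.03 to 11.19). It was at 11.35 for Wnt targets (carcinomas 11.28 to 11.45). The late adenoma of mouse 1755 was at 10.57 for cell cycle genes (carcinomas 10.50 to 10.70). The absorptive colonocyte list was at 10.51 ± 0.78 log2 in adenomas and 9.42 ± 0.37 in carcinomas (SD, n = 3 each). The median difference was -1.03, with 19 of 20 genes lower and 11 past the threshold adjusted over the list alone. The differentiation keratin Krt20 was at 11.76 ± 1.63 and 8.81 ± 1.58 (difference -2.95, SE 0.833), and Cdhr5, a protocadherin of the brush border, at -1.89 (SE 0.521). The goblet cell list was at 11.66 ± 0.70 and 10.45 ± 0.64 (median difference -0.94), with 10 of 10 lower. Past it were 3, the secreted mucin Muc2 (-1.36, SE 0.317), the resistin-like Retnlb (-2.16, SE 0.608) and the trefoil factor Tff3 (-1.28, SE 0.373). The cell cycle list was at 10.21 ± 0.40 and 10.61 ± 0.10 (median difference 0.41), with 29 of 29 higher, 14 of them at an unadjusted p under 0.05 and 0 past the threshold adjusted over the list alone. Top2a, the topoisomerase of dividing cells, was at 0.62 (SE 0.189). Wnt targets were at 10.71 ± 0.76 and 11.34 ± 0.10 (median difference 0.67), with 19 of 19 higher and 0 past it. Lgr5 was at 1.46 (SE 0.501), the Wnt inhibitor Wif1 at 1.24 (SE 0.433) and Axin2 at 0.63 (SE 0.317). Without mouse 1805 the mean difference was 0.21 for Wnt targets, in place of 0.64, and 0.19 for cell cycle genes, in place of 0.40. Without mouse 1803 it was 0.96 for Wnt targets.

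Other lists passed as well. Stem cell genes were higher by a median of 0.40 (12 of 14), macrophage genes by 0.61 (11 of 13; Lyz2 0.95) and T and NK cell genes by 0.41 (12 of 14; the signalling kinase Zap70 0.47). Enteroendocrine genes were lower by a median of -0.68 (10 of 11; the granin Chgb -1.66), hypoxia and glycolysis genes by -0.39 (13 of 13; Car9 -1.43), neutrophil genes by -0.57 (11 of 12; Ngp -0.73), squamous genes by -0.09 (10 of 12) and oxidative phosphorylation genes by -0.08 (13 of 13). Of these 8 lists only the squamous one had a member past the threshold adjusted over the list alone, the cornified envelope gene Sprr1a at -1.95 (SE 0.411). The mean of the neutrophil list, -0.53, became -0.083 without mouse 1805 and -0.30 without 2201, both ending the call, and -0.82 without 1803. That of the hypoxia list, -0.47, became -0.19 without mouse 1805 and -0.72 without 1755. The stem cell mean, 0.27, became 0.099 without mouse 1805 and 0.46 without 1755, and the call ended without 1803 (0.27). Without mouse 1803 or 2201 the calls ended for T and NK cells (0.44 and 0.26, in place of 0.43), macrophages (0.38 and 0.31, in place of 0.47) and squamous genes (-0.34 and -0.32, in place of -0.39). Oxidative phosphorylation lost its call without mouse 1755 (-0.034) or 3407 (-0.060), and was at -0.13 without 1803, in place of -0.085. The mean level of the 2 erythroid genes, not tested, was 8.47, 9.60 and 11.57 in the late biopsies of mice 1755, 1803 and 1805, and 7.75, 8.40 and 8.36 in those of mice 2201, 3407 and 3413. Adjusted p ran from 1.94e-11 to 0.0251 at the preset correlation for the 12 lists. All 12 calls were lost, at adjusted p = 0.577 with an estimated correlation for 9 of them, 0.743 for neutrophils, 0.753 for macrophages and 0.818 for oxidative phosphorylation. In 5 of the 18 other lists, median, mean and test differed in sign.

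limma called 0 genes in this comparison, with 2341 at an unadjusted p under 0.05 (1344 higher, 997 lower). Pld5 was at 6.49 ± 0.12 in adenomas and 7.67 ± 0.15 in carcinomas (difference 1.18, SE 0.154, adjusted p = 0.251). It was followed by Gas2l3, a cytoskeletal linker (0.73), the meiotic gene Mei4 (0.80) and Kansl1l (0.77). Lower were the aldo-keto reductase paralogs Akr1c13 (-0.92) and Akr1c12 (-1.16), Calml4 (-0.80) and Ano10 (-0.60), these with an adjusted p = 0.401. Mki67 was at 0.35, Pla2g2a at 0.46, Myc at 0.26, Ctnnb1 at 0.11 and Apc at -0.10. Without mouse 1803, 395 genes passed in place of 0 (122 higher, 273 lower). With age as a covariate 16 lists passed, 7 of them among the 12, and the mean of the stem cell list was -0.01. With array weights 6 lists passed, all of them among the 12.

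**Figure D3:**
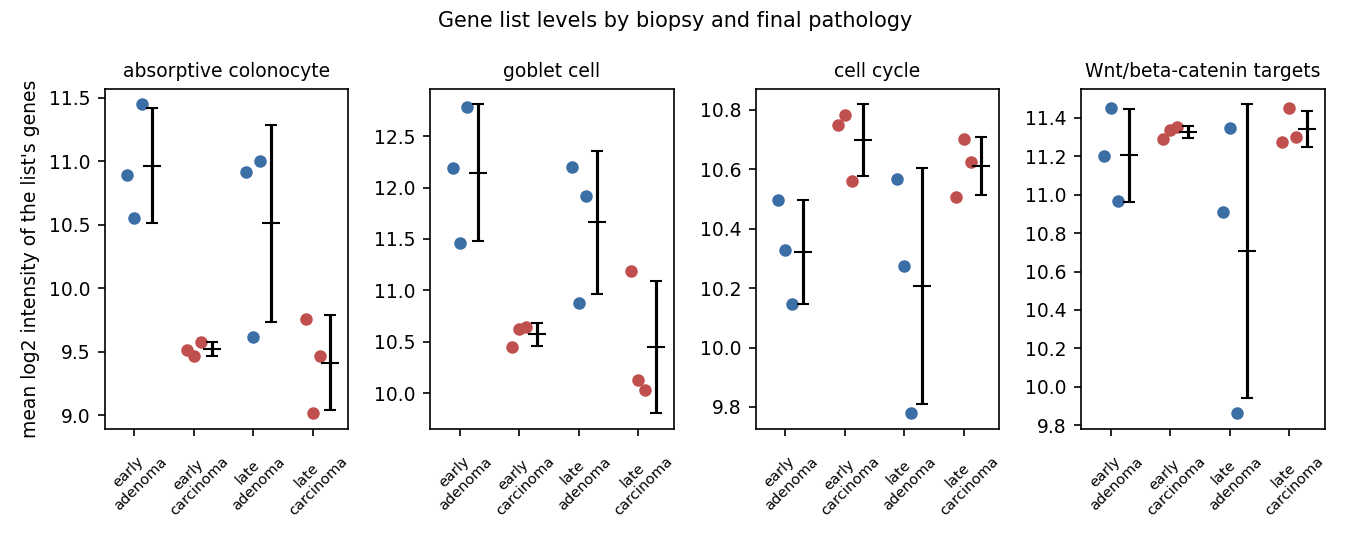
Mean log2 level (vertical axis) of the absorptive colonocyte, goblet cell, cell cycle and Wnt target lists on each array, in early and late biopsies of tumors with final pathology adenoma or intramucosal carcinoma, with the group mean ± SD (n = 3 each). The early absorptive level lies at 10.96 ± 0.45 in tumors read as adenoma at the late biopsy and at 9.52 ± 0.06 in those read as carcinoma.

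The last comparison asked whether the early biopsies already differed by the reading of the late biopsy. Early biopsies have no reading, so a tumor read as carcinoma late is not known to have been an adenoma early. In tumors read as carcinoma at the late biopsy, absorptive and goblet cell genes were lower and cell cycle genes higher at the early biopsy too, at the preset correlation. These calls were lost, at adjusted p = 0.335, 0.388 and 0.604 with an estimated correlation. The absorptive list was at 10.96 ± 0.45 log2 in the 3 tumors with a final reading of adenoma and 9.52 ± 0.06 in the 3 of carcinoma (median difference -1.44). Of its 20 genes 19 were lower and 12 past the threshold adjusted over the list alone. The carbonic anhydrase Car4 was at -4.01 (SE 0.824), the chloride exchanger Slc26a3 at -4.06 (SE 0.878) and the peptide hormone guanylin, Guca2a, at -2.11 (SE 0.459). The goblet list was at 12.14 ± 0.66 and 10.58 ± 0.11 (median difference -1.43), with 10 of 10 lower and 2 past it, Tff3 (-2.09, SE 0.373) and Muc2 (-1.07, SE 0.317). Cell cycle genes were higher by a median of 0.39, with 29 of 29 higher, 12 at an unadjusted p under 0.05 and 0 past the threshold adjusted over the list alone. Mki67 was at 0.47 (SE 0.171).

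Oxidative phosphorylation genes were lower by a median of -0.24, with 13 of 13 lower and 6 past the threshold adjusted over the list alone (Sdhb, of respiratory complex II, -0.32). Matrix genes were higher by 0.75 (17 of 17, 4 adjusted over the list alone, with Fn1 at 0.48). Endothelial genes were higher by 0.83 (10 of 10, 5 adjusted over the list alone). Kdr, a receptor for vascular endothelial growth factor, was at 1.06. Neither of these 2 lists was called in late biopsies, and the early adenoma arrays used here also enter their rise in adenoma tumors. Neutrophil genes were higher by 1.11 (11 of 12, 4 adjusted over the list alone; Cxcr2 1.54), matrix proteases by 0.70 (11 of 11, 1; the gelatinase Mmp9 1.39), mucosal defence genes by 0.65 (15 of 17, 1; Saa3 1.72) and mesenchymal transition genes by 0.33 (9 of 9, 2; Fn1 and Snai1). B and plasma cell genes were lower by a median of -0.87 (11 of 11), enteroendocrine genes by -0.36 (10 of 11) and Paneth cell genes by -0.81 (5 of 7), with 0 of each past the threshold adjusted over the list alone. With one mouse left out, mucosal defence lost its call without 2201 (mean 0.43, in place of 0.79), neutrophils without 1803 (0.61, in place of 0.79), matrix proteases without 1803 (0.57, in place of 0.69) and enteroendocrine genes without 1805 (-0.19, in place of -0.52). Mesenchymal transition lost it without 1755 (0.33), 1803 (0.26) or 3413 (0.17), and was at 0.57 without 2201, in place of 0.35. B and plasma cells lost it without 1805 (-0.024) or 2201 (-0.84), and were at -1.43 without 1755, in place of -0.95. Paneth cells lost it without 1755 (-0.86), 2201 (-1.24) or 3413 (-0.82), in place of -1.08. The matrix mean, 0.77, became 0.51 without 1803 and 0.43 without 3413. The mean level of the 2 erythroid genes, not tested, was 7.44, 7.72 and 7.54 in the early biopsies of the adenoma mice and 8.26, 7.38 and 8.10 in those of the carcinoma mice. Adjusted p for these 13 lists ran from 4.52e-16 to 0.0494 at the preset correlation. All 13 calls were lost, at adjusted p = 0.335 with an estimated correlation for the absorptive list, 0.388 for goblet cells, 0.516 for oxidative phosphorylation, 0.547 for endothelium, 0.604 for 7 lists and 0.659 for B and Paneth cells. In 4 of the 17 other lists, median, mean and test differed in sign.

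limma called 0 genes, with 2384 at an unadjusted p under 0.05 (1407 higher, 977 lower). Hp was at 7.06 ± 0.35 in the adenoma tumors and 9.67 ± 0.81 in the carcinoma tumors (difference 2.61, SE 0.358, adjusted p = 0.134). The copper carrier ceruloplasmin, Cp, was at 9.65 ± 0.29 and 11.05 ± 0.41 (difference 1.40, SE 0.212, adjusted p = 0.148). Praf2 (0.72, adjusted p = 0.134) and the cytoskeletal Septin11 (0.57) were also higher, and Zfp758 (-0.77, adjusted p = 0.134), Smim6 (-0.71), the cytochrome P450 gene Cyp2d10 (-0.82) and Selenoo (-0.48, these with adjusted p = 0.148) lower. Lgr5 was at 0.88 (SE 0.501), Krt20 at -1.89 (SE 0.833), Axin2 at 0.17, Myc at 0.05, Pla2g2a at 0.04, Ctnnb1 at 0.03 and Apc at -0.03. In the first array group, only the tumor of mouse 2201 was read as carcinoma later, and the second array group holds early arrays of carcinoma mice only. The absorptive level of mouse 2201 was 9.52 against 10.55 to 11.45 in the 3 adenoma mice of its array group. Endothelium was 8.77 against 8.62 ± 0.22 and matrix 10.07 against 9.92 ± 0.48 (SD, n = 3). With the array group as a term the difference rests mainly on mouse 2201, so a call kept with it is no support. The means were -1.57 for absorptive, -1.96 for goblet, 0.46 for cell cycle and -1.40 for B and plasma cell genes. They were 1.56 for mucosal defence (in place of 0.79), 1.25 for neutrophil (in place of 0.79) and -0.10 for oxidative phosphorylation genes (in place of -0.21). The mucosal defence level of the early biopsy of mouse 2201 was 10.73 against 9.37 ± 0.25 in the other 5 early biopsies (SD), and without that mouse the list, at 0.43, did not pass. The calls ended for matrix (0.13), endothelium (0.09), mesenchymal transition (-0.08), matrix proteases (0.71), enteroendocrine (-0.52) and Paneth cell genes (-0.84). In place of 0 genes, 326 passed with array weights (142 higher, 184 lower), 67 without mouse 1803 and 3 without mouse 2201, 2 of which, Arap3 and Layn, were named after their values were seen.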

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

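Of the tests in this part, those on the array group, the epithelial share, the final pathology and normal mucosa were chosen only after the result was seen, while the test for non-epithelial tissue in the late biopsy of mouse 1805 and the splits of the samples were planned. The lists, genes and arrays named here stood out because 1 of 6 arrays lay far from the other 5, because a list's late-early change differed between pathologies, or because of a signal in probe sets that name no gene. A sample far from the others was found in 10 of 174 groups of 6 arrays, where chance gives about 1 in 20, or 8.7.

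Endothelial and matrix genes were higher in late than in early biopsies. The 2 pairs within one array group had an endothelial change of -0.046 and the 4 pairs that cross the array groups had 1.02 to 1.40, so the array group may be the source of this change, and the gap of 0.140 between the array groups on probe sets without a gene name stood out by itself. A lower share of epithelium that raises all other cell types alike would raise T and NK cell genes as much. Endothelial genes rose by 1.19 more than T and NK cell genes over the crossing pairs (SD 0.529, n = 4). An array group shift in endothelial genes would give such a gap at any share of epithelium. The T and NK cell list was the only comparator, was picked after the result, and ranged from -0.60 to 0.74 over these pairs. Other tested lists of non-epithelial cells had mean changes there of 1.05 (matrix), 0.96 (neutrophils), 0.59 (smooth muscle) and 0.35 (macrophages). Lower were B and plasma cells (0.24), adipocytes (0.09), neurons and glia (0.08) and mast cells (-0.93). The test therefore cannot decide on a lower share, which stays open. Final pathology cannot be told apart here, since the only carcinoma pair that crosses the array groups, that of mouse 2201, changed by 1.15, inside the range of 1.02 to 1.40. Age and the time between biopsies stay open as untested.

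Absorptive and goblet cell genes were lower in early biopsies of tumors read as carcinoma at the late biopsy. The absorptive change of the 4 pairs that cross the array groups, less that of the 2 pairs within one, was 0.0022 (SD 0.522 over the 4). With the array group as the whole cause, the median difference of -1.44 would need a fall at least as large. The crossing pairs are those of the 3 adenoma mice and of mouse 2201, and the pairs within one are both of carcinoma mice. An opposite change by pathology could offset an array group shift, so this test cannot decide. It replaced, after the values were known, a test by the array group term that was left undecided. The goblet change was -0.17 ± 0.712 in the 4 and -0.56 ± 0.0836 in the 2 (SD), and late biopsies, all in one array group, still differed by an absorptive mean of -1.10. Normal mucosa in the adenoma biopsies might lower Wnt targets there, and the median difference of Wnt targets was 0.17 with a spread of 0.325 over 19 genes, which keeps this explanation open. In the late biopsies, where it was not tested, the median difference was 0.67, and the mean of 0.64 became 0.21 without mouse 1805. A difference between the tumors themselves stays open beside these, and early biopsies have no reading of their own.

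The late biopsy of mouse 1805 stood apart in several groups. Wnt target genes were at 9.86 against 11.26 ± 0.20 in the other 5 late biopsies (gap over range 0.660), Paneth cell genes at 8.98 against 11.06 ± 0.37 (0.629), Axin2 at 10.15 against 11.63 ± 0.24 (0.642) and Pla2g2a at 12.71 against 13.93 ± 0.04 (0.917). Blood or other non-epithelial tissue in place of epithelium is argued against, since 10 general epithelial genes deviated by a median of 0.47, above the -0.18 to 0.10 of the other late biopsies, but blood beside the epithelium stays open, with the red cell genes Alas2 at 11.77 against 8.84 ± 0.70 and Slc4a1 at 11.36 against 8.19 ± 0.69. Normal mucosa in place of tumor epithelium may play a part, with absorptive genes deviating by a median of 1.23, but mouse 1755 reached 1.03, so it cannot be told apart from the spread between adenomas. No biological explanation was tested.

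In other groups of 6, enteroendocrine genes of the early biopsy of mouse 1805 were at 8.39 against 7.29 ± 0.15 (gap over range 0.686), and its B and plasma cell genes at 9.80 against 7.01 ± 0.25 (0.798). Mucosal defence genes of the early biopsy of mouse 2201 were at 10.73 against 9.37 ± 0.25 (0.645), and interferon response genes of the early biopsy of mouse 1755 at 9.85 against 8.22 ± 0.21 (0.709). Pld5 in the early biopsy of mouse 1803 was at 7.13 against 6.48 ± 0.03 (0.902), and Apc in the late biopsy of mouse 2201 at 10.62 against 11.01 ± 0.04 (0.789).

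The late-early change differed between carcinoma and adenoma tumors, by the interaction test at the preset correlation, for 12 lists. The time between biopsies was unequal between the pathologies and was not a term in that test. All 12 calls were lost, at adjusted p = 0.739 to 0.831 with an estimated correlation. With the array group as a term, which leaves the difference between mouse 2201 and the 3 adenoma mice, 6 of the 12 calls ended: endothelium (mean -0.061), matrix (-0.20), mesenchymal transition (0.0058), stem cells (0.079), oxidative phosphorylation (0.054) and matrix proteases (-0.91). The median differences were -1.53 for neutrophils, -0.90 for endothelium, -0.83 for matrix proteases, -0.79 for fibroblasts and matrix, -0.47 for mesenchymal transition and -0.29 for hypoxia and glycolysis. They were 1.29 for Paneth cells, 1.28 for MHC class II, 0.56 for Wnt targets, 0.41 for T and NK cells, 0.33 for stem cells and 0.13 for oxidative phosphorylation.

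Other splits of the samples were run for each count. For late against early, 23 of 32 splits that part every pair called as many lists as the real one (real 10, highest other 19), so chance cannot be excluded for the lists. A real count of 0 genes is matched by every split whatever the data, here 32 of 32 (real 0, highest other 0), so the gene counts test nothing here, nor below where the real one is 0. The 3 pairs of a pathology make 4 splits, too few for a share under 0.05. In adenoma tumors 1 split called as many genes (real 25, highest other 0) and 3 as many lists (real 10, highest other 22); in carcinoma tumors 4 called as many genes (real 0, highest other 0) and 4 as many lists (real 8, highest other 14). The 6 mice make 10 splits into 3 and 3, again too few. For the interaction 10 called as many genes (real 0, highest other 0) and 7 as many lists (real 12, highest other 18); for late biopsies 10 as many genes (0, 0) and 3 as many lists (12, 17); for early biopsies 10 as many genes (0, 2) and 4 as many lists (13, 16).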

How the results depend on the processing

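The array group as a term was chosen only after the data were seen, and so were the tests that use it; the other alternatives were planned. Arrays give no count of molecules, and with 3 mice per pathology the precision rests on the number of arrays. The floor for linear values was not run, because the deposited values were read as log2. Except where another reason is given, the cause was not tested.

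Without the mouse block, 2 of the 25 genes in adenoma tumors passed in place of 25, and both were among the 25. Cell cycle and oxidative phosphorylation genes for late against early and mucosal defence genes in adenoma tumors also lost their calls without the pairing, 1 further list passed in carcinoma tumors (9 in place of 8), 2 others passed for late against early and 1 in adenoma tumors. With only the late arrays in place of the random block, 3 further lists passed in late biopsies (15 in place of 12), and the block changed no other call. With the estimated correlation 0 lists passed in each of the 6 comparisons, in place of 10 (late against early), 10 (adenoma tumors), 8 (carcinoma tumors), 12 (interaction), 12 (late biopsies) and 13 (early biopsies); an unadjusted p under 0.05 was reached by 2 lists in late, 2 in early biopsies and 0 elsewhere.

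In adenoma tumors the count of 25 genes was 13 and 9 without the dimmest 25% and 50% of genes, all of them among the 25, 7 over all probe sets (5 among the 25), 42 with median centring (6 higher and 36 lower, against 7 and 18), and 0 with the array group as a term (1142 at an unadjusted p under 0.05). With age in days late against early gave 33 genes in place of 0, and array weights gave 326 in place of 0 for early biopsies. With one mouse left out, genes ranged from 0 to 2 for late against early (2 without 3407), 0 to 78 in adenoma tumors (0 without 1755, 1803 or 1805, 78 without 2201, 2 without 3407, 3 without 3413), 0 to 1 in carcinoma tumors (1 without 1805), 0 to 395 for late biopsies (395 without 1803) and 0 to 67 for early biopsies (67 without 1803, 3 without 2201).

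Without the dimmest 50% of genes 6 lists passed for late against early, 4 in carcinoma tumors and 7 in late biopsies. Array weights gave 5 in carcinoma tumors, 6 in late biopsies and 8 in the interaction (7 of these among the 12), and all probe sets gave 5 in carcinoma tumors. The array group as a term gave 3 for late against early. With one mouse left out the lists ranged from 6 to 13 for late against early (6 without 3407).

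Mean changes of called lists that turned with the array group as a term were, for late against early, endothelium -0.046, matrix -0.079, macrophages -0.041, mesenchymal transition -0.074 and oxidative phosphorylation 0.0089. They were -0.079 for mesenchymal transition in adenoma tumors, and -0.046 for endothelium, -0.079 for matrix, -0.041 for macrophages and -0.24 for MHC class II in carcinoma tumors. Mesenchymal transition turned to 0.0058 in the interaction and to -0.083 in early biopsies. With one mouse left out, the means in carcinoma tumors ranged from -0.046 to 0.59 for endothelium, -0.079 to 0.61 for matrix, -0.041 to 0.48 for macrophages and -0.24 to 1.39 for MHC class II, each lowest without mouse 2201, the only carcinoma pair that crosses the array groups, which gives the same values as the term. Hypoxia genes ranged from -0.060 to 0.64 in adenoma tumors and from -0.69 to 0.0082 in the interaction, turning without mouse 1805. Stem cell genes of late biopsies turned to -0.011 with age as a covariate. Of the genes named by rank, 0 of 965 values under alternatives turned sign, against 55 of 909 for the 9 fixed genes. The ranked genes were picked on these same arrays for small p or large differences, so their unturned signs say little about stability.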

Other observations

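No tests reported in this part were chosen only after the result was seen. Of the 30 lists tested, 9 passed in no comparison. Smooth muscle contractile genes came nearest for late against early (median 0.27, adjusted p = 0.0709 from limma's cameraPR), and enteric neuron and glia genes for late biopsies (median -0.08, adjusted p = 0.0706). Interferon response genes, which cells switch on against viruses, had a median of -0.40 in early biopsies (adjusted p = 0.119), and tuft cell genes 0.22 in the interaction (adjusted p = 0.171). Fetal-like and YAP-associated genes were at 0.29 in adenoma tumors (adjusted p = 0.239) and immediate early and heat shock genes, which respond to tissue handling, at -0.11 (adjusted p = 0.322). Adipocyte genes were at -0.09 in the interaction (adjusted p = 0.398), p53 targets at 0.07 for late against early (adjusted p = 0.437) and colorectal cancer driver genes at 0.02 (adjusted p = 0.504).

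Of the erythroid list, 2 genes were measured and the list was not tested. In the late biopsy of mouse 1805, Alas2, the first enzyme of heme synthesis in red cells, was at 11.77 against 8.84 ± 0.70 in the other 5 late biopsies (SD), and Slc4a1, the band 3 anion exchanger of red cells, at 11.36 against 8.19 ± 0.69.

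In lists that did not pass for late against early over all tumors, single members passed adjusted over the list alone. Higher were the peptide hormone Pyy at 1.04 and Guca2b at 0.45. Lower were the stem cell RNA-binding protein Msi1 at -0.57, Retnlb at -0.72 and the tuft cell gene Avil at -0.39. Usp18, an interferon-induced protease, was at -1.60 and Dsg3 at -0.81. The stem cell and squamous lists, which hold Msi1 and Dsg3, did pass in carcinoma tumors at the preset correlation. In carcinoma tumors Pyy was at 1.37 and Retnlb at -0.97, and both passed adjusted over the list alone in lists that did not pass.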
